A study of Mus musculus with 12 samples.

How the data were processed

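Poly(A) RNA was measured in brains of C57BL/6N mice, a common laboratory strain, at 6 weeks of age. Per the labels' protocols, the mice were wild type or homozygous for a point mutation of Wdr4 placed in the genome with CRISPR-Cas9 (knock-in), RNA was extracted with TRIzol, and libraries came from a stranded mRNA kit. From each genotype there were 3 libraries of total mRNA (input) and 3 libraries of mRNA bound to ribosome nascent-chain complexes (RNC), that is, mRNA recovered together with ribosomes that carry a growing peptide. The mutated samples carry a short name in the column headers that was read as homozygous. Groups were taken from the sample labels, and every library entered exactly 1 of the 4 groups.

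The values are TPM made by the authors and deposited as a table of 18251 genes by 12 libraries; the headers spell the unit with its letters in another order. Per the submitters' processing notes, TopHat2 and HTSeq were used with the mouse build mm10; their versions, settings and annotation are not given in the sources used here. The values of a library summed to between 547645 and 649896, so part of each library's total lay in genes outside the table. TPM keeps no absolute depth, so the number of reads behind a value is unknown and no counting interval or detection floor was computed. A value of 0 is reported as listed at 0. Since TPM are shares of a total, a change in a few abundant transcripts, such as those of the mitochondrial genome, shifts every other gene of that library. Reads shared between near-identical genes (Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt) can be split or lost in such counting, so those values are uncertain.

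Gene symbols are those of the table; 17981 of them occurred in the mouse gene name table and 17645 were protein-coding in the RefSeq annotation of GRCm38.p6, the assembly that mm10 renders, from which positions (1-based) were taken; 380 symbols had no match there. No column was left unused.

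Values were transformed to log2(TPM + 1), so fold changes are on that scale and understate the change of low genes. The 12232 genes with at least 1 TPM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 (mean-variance trend, robust empirical Bayes), with 1 fit of the 4 group means over all 12 libraries (8 residual degrees of freedom), so that the groups share an estimate of the spread. The same fit gave 5 contrasts: knock-in minus wild type in input and in RNC, the interaction of genotype and fraction (the change of the translation ratio, that is, the RNC change minus the input change), and RNC minus input in each genotype. Adjusted p-values are Benjamini-Hochberg values over the 12232 genes, two-sided, with 0.05 as the threshold. A rank or permutation test of 3 libraries against 3 cannot give a p under 0.1, so no such test was used for single genes. Errors of fold changes are limma standard errors, and errors of TPM are standard deviations over 3 libraries.

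Before the data were examined, 45 gene lists were fixed (27 of pathways and complexes, 18 of cell type and brain region markers), together with the design, the alternatives and the rule for named genes. Lists with at least 5 tested genes, 41 of them, were tested with camera at a preset correlation between genes of 0.01, adjusted over the 41 lists within a comparison; camera with an estimated correlation and fry were run as alternatives. Beside each list stands the number of members past the test over all genes and, where above 0, the number adjusted over the list alone. List medians are given relative to the median of all tested genes of that contrast. The lists of noncoding RNAs, histones, Y-linked genes and pituitary markers had fewer than 5 tested genes and were not tested.

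The rule for named genes took, for each genotype comparison, the 12 higher and 12 lower genes with the smallest unadjusted p among those past the threshold with a mean of at least 1 TPM in a compared group, leaving out clone and model names. Where fewer than 5 passed in a direction, genes with the next smallest p filled up to 5 and are given as values. For each fraction comparison it took the 10 higher and 10 lower genes with the largest change past the threshold and a mean of at least 5 TPM. For each list it allowed up to 4 members, those past the threshold first and then by p, and it always included Wdr4 and Mettl1.

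Each count was recomputed with quantile normalization, without the mean-variance trend, without the filter, with a filter of 5 TPM, with a pseudocount of 0.1, on the 6 libraries compared alone, with the replicate number as a block, and without each library in turn. Quantile normalization sets values by rank. It holds genes near the top of every library, such as the mitochondrially encoded ones, close to no change, so it cannot decide whether these genes changed. The translation ratio was also recomputed without each brain, taken as the input and RNC library of the same genotype and number. Alternatives added after the libraries had been seen were leaving out the 4 libraries numbered 3, the number as a block in all 12 libraries, the Y-linked genes as a covariate, the brain as a random effect (consensus correlation 0.686), and leaving out the 13 mitochondrially encoded genes. The labels do not say that equal numbers mean the same animal. Whether they pair libraries was checked by correlating each library's deviations from its group mean across genes. Equal numbers correlated at 0.573 to 0.715 between knock-in input and RNC, 0.458 to 0.656 between wild-type input and RNC, 0.131 to 0.212 between genotypes in input and 0.328 to 0.586 between genotypes in RNC, and 6 of 6 input libraries correlated best with the RNC library of their own number. Within a genotype the numbers were therefore read as pairing input with RNC. Between genotypes the pairing stays unsettled. Deviations from a group mean cancel within the group, so equal numbers can correlate when number 3 alone stands apart in both genotypes. Unequal numbers were not compared between genotypes, so the genotype block rests on an unsettled pairing. Values with the block are given where they change a call. The block left 2 residual degrees of freedom in the genotype comparisons and 4 in the others.

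The fit was tested on simulated data with known changes, drawn for the 12232 genes with 100 genes at each size. At a log2 change of 1 it recovered 32% of them in input, 35% in RNC and 8% for the translation ratio; at 2 it recovered 88%, 92% and 49%. Unchanged genes made up 4%, 3.79% and 1.72% of the simulated calls. The noise was drawn independently for each gene and library. It lacks the deviations that the genes of a library and the libraries of a brain share in these data, so these rates need not hold for them. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. A planned comparison of codon content with the translation ratio was not run, because no transcript sequences were used here. The labels do not state whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Ddx3y and Eif2s3y, which are Y-linked, were present in some libraries of each genotype and listed at 0 in others, so each genotype came from at least 2 animals.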

Results

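Ribosome-bound and total mRNA were profiled in the brain to ask which genes are translated differently when Wdr4 is mutated. WDR4 and METTL1 form the enzyme that places N7-methylguanosine (m7G) on tRNAs. The 12 libraries fell into 4 groups of 3: input of wild-type brains, input of knock-in brains, RNC of wild-type brains and RNC of knock-in brains. The table gave TPM for 18251 genes, of which 12232 were tested. Its values summed to 547645 TPM in wild-type input 3 and up to 649896 TPM in wild-type RNC 2.

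The libraries numbered 3 stood apart in composition. Transcripts of the 13 mitochondrially encoded genes held 58.1% of the summed TPM in wild-type input 3 against 41.5% and 41.4% in the other wild-type inputs. They held 36.1% and 39.5% in the wild-type and knock-in RNC libraries numbered 3, against 16.9% to 22.8% in the other RNC libraries. In knock-in input 3 the share was 36.8%, against 40.9% and 40.7%. The median gene had 1.02 TPM in wild-type input 3 and 2.16 to 3.76 TPM in the other libraries. Across genes, which are not independent replicates, libraries 1 and 2 of a group correlated at 0.993 to 0.996 and either of them with number 3 at 0.958 to 0.980. The Y-linked transcripts Ddx3y and Eif2s3y stood at 2.32 TPM or more in the libraries of knock-in 1, knock-in 3 and wild type 3 and were listed at 0 in the others. Sexes were thus mixed within both genotypes and unequally between them.

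**Figure D1:**
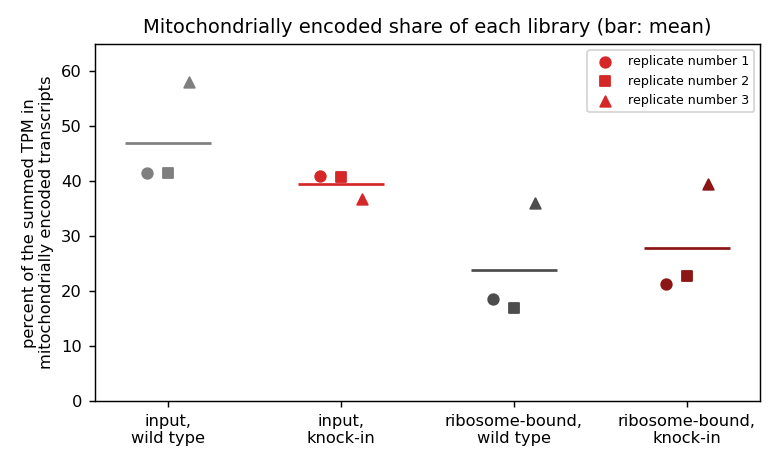
Share of the summed TPM held by mitochondrially encoded transcripts, in percent, for each of the 12 libraries by group, with the replicate number. Wild-type input 3 lies at 58.1%, and the RNC libraries numbered 3 lie at 36.1% and 39.5%, above the other libraries of their groups.

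Wdr4 (chromosome 17, 31494322 to 31519985) carries the point mutation, so its mRNA level does not check the labels. It was listed at 4.96, 4.95 and 2.16 TPM in the wild-type inputs and 5.38, 5.21 and 7.46 TPM in the knock-in inputs. In RNC it was listed at 6.22, 7.21 and 4.73 TPM in wild type and 6.92, 6.76 and 5.65 TPM in knock-in. Its log2 change was 0.53 ± 0.27 (SE) in input (adjusted p = 0.539) and 0.09 ± 0.27 in RNC (adjusted p = 1). Mettl1, its catalytic partner (chromosome 10, 127041549 to 127046365), stood at 8.42 ± 3.92 TPM in wild-type and 9.12 ± 1.65 TPM in knock-in input (SD, n = 3; adjusted p = 0.693). In RNC it stood at 11.8 ± 3.69 and 9.97 ± 1.27 TPM. Its change in input turned from 0.20 to -0.35 without the libraries numbered 3 (adjusted p = 0.0229), and that in RNC went from -0.18 to -0.39 (adjusted p = 0.0145). Positions here and below are on mm10 (GRCm38.p6), and each gene given one is protein-coding. Neither the list of 5 genes around the m7G enzyme nor that of 43 tested tRNA modification enzymes had a member past the test in either fraction. Their medians relative to all genes were 0.01 and 0.01 in input and -0.06 and 0.05 in RNC.

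The first comparison asked how mRNA levels differed between knock-in and wild-type brains, and genes driven by the transcription factors ATF4 and CHOP in the integrated stress response led it. Atf5, a transcription factor of that response (chromosome 7, 44812256 to 44816658), rose from 22.2 ± 3.58 TPM in wild type to 162 ± 23.8 TPM in knock-in (SD, n = 3 each). Ddit3, which encodes CHOP (chromosome 10, 127290793 to 127296291), rose from 23.3 ± 0.753 to 100.2 ± 7.08 TPM. Chac1, which breaks down glutathione (chromosome 2, 119351242 to 119354326), rose from 9.47 ± 3.57 to 52.1 ± 8.26 TPM. Trib3, a pseudokinase induced by CHOP (chromosome 2, 152337425 to 152344060), rose from 0.269 ± 0.0838 to 7.64 ± 2.81 TPM. Gdf15, a secreted stress hormone (chromosome 8, 70629393 to 70632470), was at 0.181 ± 0.186 TPM in wild type and rose to 4.91 ± 1.12 TPM. Adm2, a secreted peptide of the calcitonin family (chromosome 15, 89322720 to 89324731), was listed at 0 in the 3 wild-type inputs and at 4.39, 4.44 and 5.22 TPM in the knock-in inputs (adjusted p = 4.02e-07).

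On the log2(TPM + 1) scale the changes were 2.82 ± 0.20 (SE) for Atf5 (adjusted p = 1.61e-05) and 2.72 ± 0.22 for Trib3 (adjusted p = 4.93e-05). They were 2.40 ± 0.31 for Chac1 (adjusted p = 0.00464), 2.32 ± 0.21 for Gdf15 (adjusted p = 0.000104) and 2.05 ± 0.20 for Ddit3 (adjusted p = 0.000226). Nupr1, a stress-induced chromatin protein (chromosome 7, 126623246 to 126625470), rose by 1.82 ± 0.21 (adjusted p = 0.00195). Eif4ebp1, a brake on cap-dependent translation (chromosome 8, 27260327 to 27275656), rose by 1.15 ± 0.16 (adjusted p = 0.0095). Mthfd2, a mitochondrial enzyme of one-carbon metabolism (chromosome 6, 83305704 to 83326011), rose by 1.65 ± 0.25 (adjusted p = 0.0112). Of the 30 tested genes of the list of integrated stress response targets, 11 rose, 0 fell and 19 did not pass, and 21 were higher when adjusted over the list alone. The list's median lay 0.83 above that of all genes (camera adjusted p = 8.47e-41). That call was lost at adjusted p = 0.0727 with an estimated correlation.

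Outside that list, Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102897200), rose from 66.9 ± 11.1 to 182 ± 42.1 TPM (log2 change 1.42 ± 0.21, adjusted p = 0.0112). Of the other 12 tested astrocyte markers 0 passed, and their list was not called (median 0.02). Cox6a2, a cytochrome c oxidase subunit of muscle and of some interneurons (chromosome 7, 128205435 to 128206366), rose from 26.4 ± 6.79 to 77.7 ± 10.4 TPM (adjusted p = 0.0112). Foxf1, a transcription factor of mesenchymal cells (chromosome 8, 121084386 to 121088154), rose from 0.462 ± 0.158 to 2.2 ± 0.686 TPM (adjusted p = 0.0112). The only gene that fell was Gabra6, a GABA receptor subunit of cerebellar granule cells (chromosome 11, 42306437 to 42321072), from 24.3 ± 7.71 to 7.18 ± 2.14 TPM (log2 change -1.60 ± 0.30, adjusted p = 0.0487). The genes next to it in p were Mybpc3 (-1.34 ± 0.28, adjusted p = 0.0962), Crtam (-1.07 ± 0.23, 0.0988), Septin2 (-1.23 ± 0.29, 0.149) and Bcl2l15 (-0.73 ± 0.18, 0.169).

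In all, 32 of 12232 genes passed in input, 31 higher and 1 lower, and 1072 had an unadjusted p under 0.05. The 3 libraries of the groups did not overlap for 2413 genes (19.7%, with 10% given by chance). The median change of all genes was 0.31. Without the 4 libraries numbered 3 it was 0.04, and 2608 genes passed, 1791 higher and 817 lower, 30 of the 32 among them. Quantile normalization, which sets the median change to -0.01, called 34 higher and 13 lower, and leaving out the mitochondrially encoded genes called 60 higher and 13 lower. With the number as a block, 2 genes passed, Adm2 (adjusted p = 0.0129) and Trib3 (0.0468), with 600 at an unadjusted p under 0.05. The blocked adjusted p was 0.0727 for Atf5 and Gdf15, 0.234 for Ddit3, 0.268 for Chac1, 0.299 for Eif4ebp1, 0.362 for Nupr1, 0.399 for Mthfd2, 0.445 for Foxf1 and 0.519 for Gfap, Cox6a2 and Gabra6. Leaving out a library took the count to 13 (wild-type input 1), 9, 13 and 6 (knock-in inputs 1, 2 and 3) and 18 (wild-type RNC 1). The calls of Chac1 (adjusted p = 0.057), Eif4ebp1 (0.0623), Foxf1 (0.057), Gfap (0.0681), Cox6a2 (0.0652) and Mthfd2 (0.0681) ended without knock-in input 3. Those of Foxf1 (0.0517), Gfap (0.0779), Cox6a2 (0.0807) and Mthfd2 (0.0645) ended without knock-in input 1. Those of Eif4ebp1 (0.052), Cox6a2 (0.052) and Mthfd2 (0.0735) ended without knock-in input 2, and those of Eif4ebp1 (0.0501) and Cox6a2 (0.0676) without wild-type input 1. Gabra6 lost its call without wild-type inputs 1 and 2 (adjusted p = 0.23 and 0.205) and the 3 knock-in inputs (0.228, 0.0736 and 0.293). It also lost it without the 3 wild-type RNC libraries (0.0903, 0.0883 and 0.0575) and knock-in RNC 1 and 3 (0.0664 and 0.0604). Under quantile normalization the adjusted p was 0.11 for Nupr1 and 0.225 for Cox6a2. Gabra6 lost its call as well without the mean-variance trend (0.0506), without a filter (0.0862), with a filter of 5 TPM (0.0558) and with a pseudocount of 0.1 (0.0521), and Cox6a2 without the mitochondrially encoded genes (0.116). On the 6 libraries alone the adjusted p was 0.0592 for Nupr1, 0.0814 for Eif4ebp1, 0.1 for Foxf1, 0.11 for Gfap, 0.113 for Cox6a2, 0.103 for Mthfd2 and 0.206 for Gabra6.

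**Figure D2:**
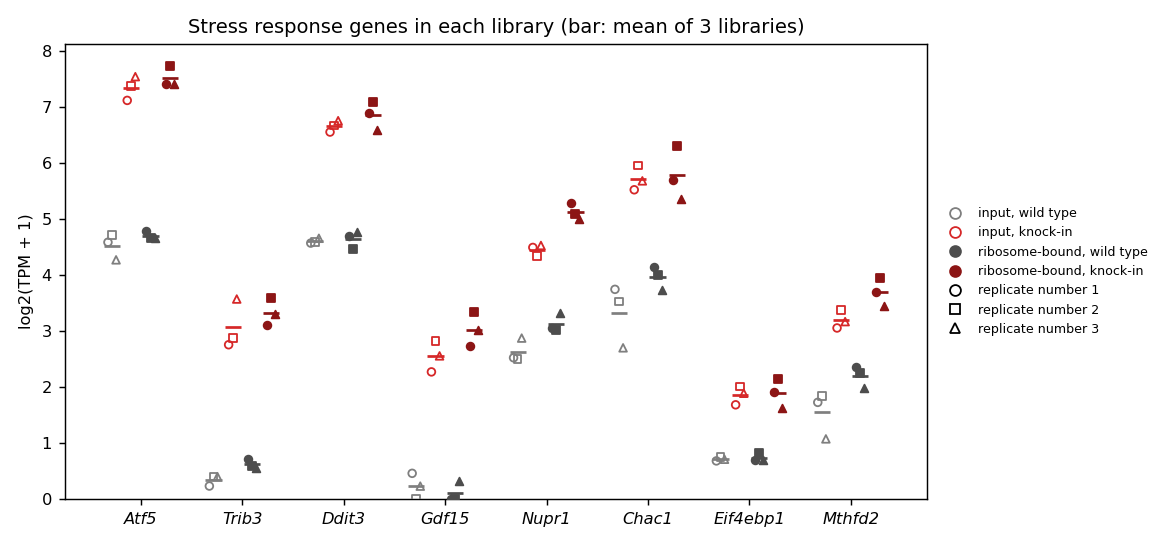
Level of 8 integrated stress response genes, as log2(TPM + 1), in each of the 12 libraries by group, with group means. Knock-in libraries lie above wild-type libraries of the same fraction, with mean changes in input of 2.82 for Atf5 and 1.15 for Eif4ebp1.

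Among the marker lists, endothelial and pericyte markers lay 0.25 above all genes in input (camera adjusted p = 4.27e-10, lost at adjusted p = 0.0727 with an estimated correlation). Of 13 tested, 2 rose, 0 fell and 11 did not pass, and 9 were higher when adjusted over the list alone. Cldn5, a tight junction protein of brain endothelium, rose from 62.4 ± 14.9 to 155 ± 33.3 TPM (adjusted p = 0.0349) and Rgs5, a pericyte regulator of G protein signalling, from 4.67 ± 0.736 to 12.8 ± 0.534 TPM (adjusted p = 0.017). Both calls ended when any 1 of several libraries was left out. Without knock-in inputs 1, 2 and 3 the adjusted p was 0.0682, 0.179 and 0.278 for Cldn5 and 0.0996, 0.101 and 0.0652 for Rgs5, and without wild-type input 1 it was 0.186 and 0.0752. Cldn5 also lost its call without wild-type input 2 (0.124) and each of wild-type RNC 1 and 2 and knock-in RNC 1, 2 and 3 (0.0573 to 0.0634), and Rgs5 without wild-type RNC 1 (0.0553). Both lost it under quantile normalization (0.313 and 0.0674) with the block (0.519 and 0.638) and on the 6 libraries alone (0.185 and 0.276). Cldn5 lost it too without the mean-variance trend (0.0507), without a filter (0.074) and without the mitochondrially encoded genes (0.285). The cerebellar list lay -0.40 from all genes (camera adjusted p = 2.24e-16, lost at adjusted p = 0.0727 with an estimated correlation), with Gabra6 past the test of 13 and 2 lower when adjusted over the list alone. Other granule cell genes were Neurod1, at 85.7 ± 18.9 TPM in wild type and 44.0 ± 5.51 TPM in knock-in (adjusted p = 0.247), and Cbln1, at 222 ± 48.4 and 145 ± 33.1 TPM. Blood markers lay at -0.99 by median and -0.37 by mean (camera adjusted p = 8.95e-15, lost at adjusted p = 0.06 with an estimated correlation). Of 7 tested, 2 lay above the median of all genes, 0 passed over all genes and 4 were lower when adjusted over the list alone. The haemoglobin genes Hba-a1 and Hbb-bs stood at 554 ± 34.7 and 401 ± 115 TPM in wild type and at 325 ± 105 and 244 ± 53 TPM in knock-in.

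Pathway lists for interferon, tRNA charging and p53 were called higher in input. The 21 interferon and antigen presentation genes lay 0.29 above all genes (camera adjusted p = 2.36e-08, lost at adjusted p = 0.245 with an estimated correlation), with 0 past the test and 11 higher when adjusted over the list alone. Isg15, a ubiquitin-like interferon product, stood at 5.88 ± 1.28 and 14.7 ± 2.37 TPM (adjusted p = 0.188). The 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, lay 0.40 above (camera adjusted p = 1.4e-05, lost at adjusted p = 0.857 with an estimated correlation), with 0 past the test and 8 higher when adjusted over the list alone. Cars, for cysteine, stood at 3.41 ± 1.2 and 9.89 ± 0.897 TPM (adjusted p = 0.0573). The 15 p53 targets lay 0.16 above (camera adjusted p = 0.0054, lost at adjusted p = 0.857 with an estimated correlation), with 2 higher also when adjusted over the list alone. These were Cdkn1a, an inhibitor of the cell cycle, from 17.3 ± 0.627 to 65.6 ± 27.7 TPM (adjusted p = 0.0296), and Bbc3, a trigger of apoptosis, from 2.64 ± 0.911 to 8.53 ± 2.65 TPM (adjusted p = 0.0379). Cdkn1a lost its call without wild-type inputs 1, 2 and 3 (adjusted p = 0.107, 0.0799 and 0.0516), knock-in inputs 2 and 3 (0.169 and 0.24), wild-type RNC 1 and 2 (0.0604 and 0.0546) and all libraries numbered 3 (0.0557). Bbc3 lost it without any 1 library other than wild-type RNC 3 (0.0516 to 0.24, highest without knock-in input 3). The block gave 0.519 for Cdkn1a and 0.638 for Bbc3, and quantile normalization gave 0.202 for Cdkn1a. On the 6 libraries alone the adjusted p was 0.129 and 0.269, and without a filter 0.074 for both. A pseudocount of 0.1 gave 0.0518 for Bbc3, and leaving out the mitochondrially encoded genes 0.0901 for Cdkn1a.

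The other lists called in input had 0 members past the test. Higher were immediate early genes (0.40, camera adjusted p = 0.0187), meningeal markers (0.15, 0.0199; 2 members when adjusted over the list alone) and ependymal markers (0.05, 0.0411), with adjusted p = 0.907, 0.907 and 0.668 with an estimated correlation. Cholesterol synthesis (-0.28, camera adjusted p = 1.78e-08) and glycolysis (-0.20, 0.00326) were lower, with adjusted p = 0.668 and 0.907 with an estimated correlation. Lower too were synaptic vesicle genes (-0.10, 0.0153), ion channels (-0.15, 0.0264), striatal markers (-0.16, 0.0264), GABA genes (-0.09, 0.0178) and the proteasome (-0.12, 0.0364), each at adjusted p = 0.907 with an estimated correlation, and heat shock proteins (-0.06, 0.00764; 0.803). Cytosolic ribosomal proteins (-0.27, camera adjusted p = 6.82e-11), oxidative phosphorylation (-0.19, 2.22e-08), mitochondrially encoded proteins (-0.53, 3.64e-12) and mitochondrial ribosomal proteins (-0.12, 0.0317) were lower at adjusted p = 0.668, 0.255, 0.309 and 0.907 with an estimated correlation. These 4 rested on wild-type input 3: without it the adjusted p was 0.0396, 0.316, 0.197 and 0.536. All but the mitochondrially encoded list then pointed in the opposite direction. Without all libraries numbered 3 the medians were 0.04, 0.03, -0.06 and 0.00. Quantile normalization, which holds the most abundant genes close to no change, put the mitochondrially encoded list at 0.00 (0.977) and cannot decide its change. Of the calls in this paragraph, 8 ended without wild-type input 1 (0.0819 to 0.578), 8 without wild-type input 2 (0.0514 to 0.206) and that of heat shock proteins without wild-type input 3 (0.113). Another 5 ended without knock-in input 1 (0.0536 to 0.368), 2 without knock-in input 2 (0.0863 and 0.704) and 6 without knock-in input 3 (0.0675 to 0.954, that of GABA genes turning). The block ended those of GABA genes (0.233), ion channels (0.102) and ependymal markers (0.0932). Quantile normalization ended those of heat shock proteins (0.293), synaptic vesicle genes (0.355), GABA genes (0.17), ion channels (0.232), ependymal (0.187) and striatal markers (0.0846). The other 19 lists were not called, with medians from -0.14 to 0.05.

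**Figure D3:**
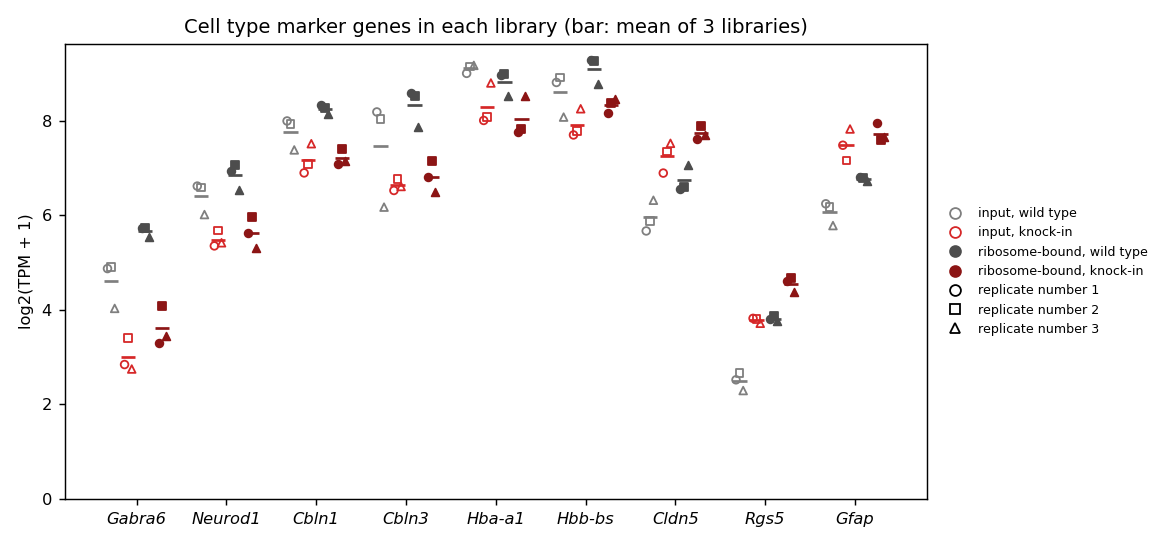
Level of cerebellar (Gabra6, Neurod1, Cbln1, Cbln3), haemoglobin (Hba-a1, Hbb-bs), vascular (Cldn5, Rgs5) and astrocyte (Gfap) genes, as log2(TPM + 1), in each of the 12 libraries by group, with group means. Gabra6 averages 24.3 and 49.9 TPM in wild-type input and RNC and 7.18 and 11.6 TPM in knock-in.

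The second comparison addressed the question the series states, which ribosome-bound mRNAs differ between the genotypes. The same stress genes led in RNC. Gdf15 rose from 0.0829 ± 0.144 TPM in wild type to 7.25 ± 1.72 TPM in knock-in (SD, n = 3 each; log2 change 2.92 ± 0.21, adjusted p = 1.05e-05), and Atf5 from 25 ± 1.45 to 184 ± 24.6 TPM (2.82 ± 0.20, adjusted p = 1.05e-05). Trib3 rose from 0.536 ± 0.0993 to 9.12 ± 1.73 TPM (2.71 ± 0.22, adjusted p = 3.92e-05), Ddit3 from 24 ± 2.6 to 117 ± 20.1 TPM (2.22 ± 0.20, adjusted p = 8.69e-05) and Nupr1 from 7.78 ± 1.08 to 33.9 ± 3.48 TPM (1.99 ± 0.21, adjusted p = 0.000671). Adm2 was listed at 0 in the 3 wild-type RNC libraries and at 3.42, 4.15 and 3.87 TPM in knock-in (adjusted p = 1.46e-06). These 6 genes passed in every alternative that tested them, the block included; the filter of 5 TPM left Adm2 out. Of the 30 integrated stress response genes, 9 rose, 0 fell and 21 did not pass, 14 were higher when adjusted over the list alone, and the same 9 genes had risen in input. The list's median lay 0.83 above all genes (camera adjusted p = 9.93e-50, lost at adjusted p = 0.0818 with an estimated correlation).

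Further genes rose in RNC at lower significance. Eif4ebp1 rose by 1.16 ± 0.16 (adjusted p = 0.00858), Mthfd2 from 3.61 ± 0.604 to 12.1 ± 2.26 TPM (adjusted p = 0.0288) and Cox6a2 by 1.52 ± 0.23 (adjusted p = 0.0152). Cxcl1, a neutrophil chemokine, rose by 1.03 ± 0.17 (adjusted p = 0.0262) and Lyz2, the lysozyme of myeloid cells, by 1.32 ± 0.22 (adjusted p = 0.0301). Hsd17b1, an enzyme of oestrogen synthesis, was listed at 0 in the 3 wild-type RNC libraries and at 1.14, 2.21 and 2.30 TPM in knock-in (adjusted p = 0.0152). Gabra6 fell from 49.9 ± 3.98 to 11.6 ± 3.82 TPM (-2.05 ± 0.30, adjusted p = 0.0147). Crtam, a receptor of T cells that is also found in brain (chromosome 9, 40972798 to 41004628), fell from 5.27 ± 0.663 to 0.97 ± 0.353 TPM (-1.68 ± 0.23, adjusted p = 0.00858). Mybpc3, a myosin-binding protein best known from heart (chromosome 2, 91118114 to 91136516), fell from 5.29 ± 1.34 to 0.706 ± 0.307 TPM (-1.88 ± 0.28, adjusted p = 0.0152), and Emilin3, an extracellular matrix protein, fell from 1.42 ± 0.207 to 0.249 ± 0.064 TPM (-0.95 ± 0.15, adjusted p = 0.0159). Neurod1 was next, at 116 ± 21.3 and 49.4 ± 11.5 TPM (adjusted p = 0.123, and 0.0123 with the block).

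In RNC 21 genes passed, 17 higher and 4 lower, with 371 at an unadjusted p under 0.05 and a median change of all genes of -0.06. The libraries did not overlap for 933 genes (7.63%, with 10% given by chance). With the block 84 genes passed, 45 higher and 39 lower, 17 of the 21 among them. Without the 4 libraries numbered 3 the count was 3099, 661 higher and 2438 lower, all 21 among them. Quantile normalization gave 32 higher and 17 lower. The block took Cxcl1 and Lyz2 to an adjusted p of 0.0525, and quantile normalization took Hsd17b1 to 0.0751, Cox6a2 to 0.0915, Cxcl1 to 0.17 and Lyz2 to 0.0802. The calls of Cxcl1 (0.13) and Emilin3 (0.132) ended without the mean-variance trend, those of Cxcl1 (0.195) and Mthfd2 (0.0792) with a pseudocount of 0.1, and those of Cxcl1 (0.118) and Lyz2 (0.104) on the 6 libraries alone. Those of Cox6a2 (0.0619) and Cxcl1 (0.069) ended without the mitochondrially encoded genes, and those of Hsd17b1 (0.158) and Lyz2 (0.0596) with the brain as a random effect. Leaving out a library took the count to 37 (wild-type input 3), 13 and 10 (knock-in inputs 1 and 3), 8 and 11 (wild-type RNC 1 and 2) and 7, 10 and 12 (knock-in RNC 1, 2 and 3). Without wild-type RNC 1 the calls of Eif4ebp1 (0.084), Hsd17b1 (0.084), Cox6a2 (0.11), Mthfd2 (0.11), Lyz2 (0.263), Crtam (0.0537), Gabra6 (0.0865), Mybpc3 (0.104) and Emilin3 (0.11) ended. Without wild-type RNC 2 those of Hsd17b1, Cox6a2, Gabra6 and Mybpc3 (0.0745 each), Cxcl1 (0.162), Mthfd2 (0.142) and Lyz2 (0.216) ended. Without knock-in RNC 1 those of Eif4ebp1 (0.0596), Cox6a2 (0.129), Cxcl1 (0.124), Mthfd2 (0.16), Lyz2 (0.27), Crtam (0.0692), Gabra6 (0.112), Mybpc3 (0.0596) and Emilin3 (0.129) ended. Without knock-in RNC 2 those of Eif4ebp1 (0.054), Hsd17b1 (0.0937), Cox6a2 (0.0772), Cxcl1 (0.0987), Mthfd2 (0.204), Lyz2 (0.129), Mybpc3 (0.118) and Emilin3 (0.0928) ended. Without knock-in RNC 3 those of Hsd17b1 (0.0568), Cox6a2 (0.0541), Cxcl1 (0.108), Mthfd2 (0.0534), Lyz2, Gabra6 and Mybpc3 (0.0551 each) and Emilin3 (0.0547) ended, and without wild-type RNC 3 those of Cxcl1 (0.0762), Mthfd2 (0.136) and Emilin3 (0.0585). Input libraries enter through the shared spread: knock-in input 1 ended the calls of Cxcl1 (0.053), Mthfd2 (0.0595) and Lyz2 (0.0663), and knock-in input 2 those of Mthfd2 (0.0516) and Lyz2 (0.0632). Without knock-in input 3 those of Cxcl1, Mthfd2, Lyz2, Hsd17b1, Mybpc3 and Emilin3 ended (0.0542 to 0.0631), and without wild-type inputs 1 and 2 that of Lyz2 (0.0563 and 0.0561).

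Between input and RNC, 14 genes were called higher in both and 1 lower in both, where 0.0431 and 0.000327 would be shared by independent lists. This expectation leaves out that both fractions share brains by number.

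**Figure D4:**
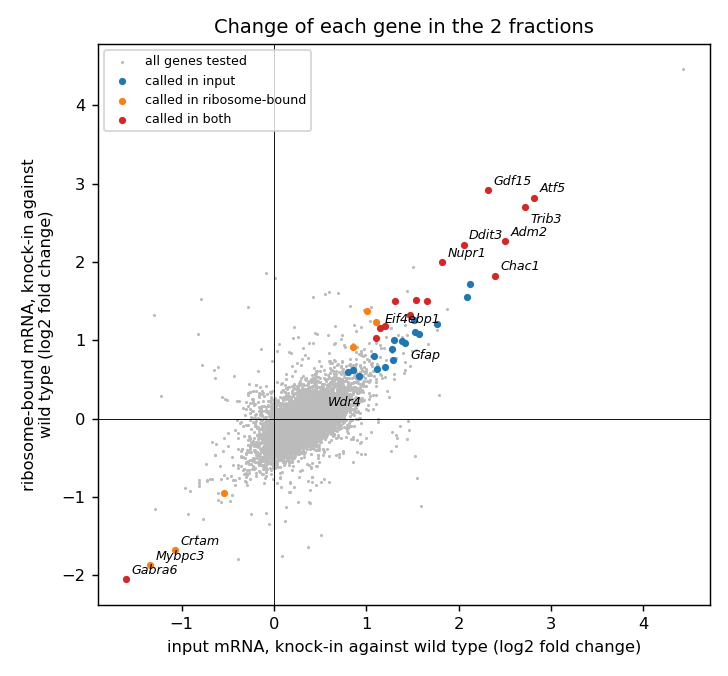
Log2 change of each tested gene between knock-in and wild type in input (horizontal axis) against RNC (vertical axis), on the log2(TPM + 1) scale, with called genes marked. In both fractions 14 genes are called higher and Gabra6 is called lower.

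Among marker lists in RNC, cerebellar markers lay at -0.53 (camera adjusted p = 9.66e-14, lost at adjusted p = 0.118 with an estimated correlation), with Gabra6 past the test of 13, 5 lower when adjusted over the list alone and 5 with the block. Cbln1, a secreted synapse organizer of granule cells, stood at 305 ± 19.3 TPM in wild type and 148 ± 17.6 TPM in knock-in (adjusted p = 0.146, and 0.0251 with the block), and Cbln3 at 328 ± 82.8 and 114 ± 26.3 TPM (adjusted p = 0.436, and 0.0124 with the block). Endothelial and pericyte markers lay 0.46 above all genes (camera adjusted p = 1.21e-10, lost at adjusted p = 0.0818 with an estimated correlation), with 0 of 13 past the test and 2 higher when adjusted over the list alone; Cldn5 stood at 108 ± 21.9 and 214 ± 20.5 TPM (adjusted p = 0.232). Meningeal (0.36, camera adjusted p = 2.08e-07) and ependymal markers (0.29, 0.00156) were higher, at adjusted p = 0.476 and 0.356 with an estimated correlation. Gfap stood at 108 ± 2.95 and 213 ± 29.1 TPM (adjusted p = 0.178, and 0.0255 with the block), and the astrocyte list was not called (-0.18). Blood markers lay at -0.71 by median and 0.04 by mean (camera adjusted p = 0.000821, lower; adjusted p = 0.45 with an estimated correlation), with 0 of 7 past the test and 4 lower when adjusted over the list alone, and the call ended without knock-in RNC 1 (0.193) and with the block (0.305).

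Of the pathway lists in RNC, interferon and antigen presentation genes lay 0.61 above all genes (camera adjusted p = 1.41e-16, lost at adjusted p = 0.0818 with an estimated correlation), with 0 of 21 past the test. The antigen-presenting H2-Aa stood at 3.08 ± 0.586 and 6.87 ± 2.19 TPM (adjusted p = 0.784). Aminoacyl-tRNA synthetases lay 0.32 above (camera adjusted p = 5.31e-05, lost at adjusted p = 0.717 with an estimated correlation), with 0 of 20 past the test and Cars higher when adjusted over the list alone (adjusted p over all genes = 0.256, and 0.0128 with the block). Cytosolic ribosomal proteins lay 0.20 above (camera adjusted p = 5.42e-12, lost at adjusted p = 0.605 with an estimated correlation), with 0 of 81 past the test; Rpl13a stood at 611 ± 16.5 and 825 ± 101 TPM. p53 targets (0.23, camera adjusted p = 0.0022; 2 members when adjusted over the list alone), mitochondrially encoded proteins (0.31, 0.000446) and immediate early genes (0.18, 0.0241) were higher at adjusted p = 0.717, 0.717 and 0.917 with an estimated correlation. Lower were cholesterol synthesis (-0.38, camera adjusted p = 4.27e-09), glycolysis (-0.28, 1.97e-06), synaptic vesicle genes (-0.20, 6.57e-05), and myelin (-0.17, 0.000366), neuronal (-0.24, 0.000573), striatal (-0.15, 0.0172) and midbrain markers (-0.07, 0.0172). Lower too were ion channels (-0.16, 0.00429), heat shock proteins (-0.15, 0.0231), glutamate receptor genes (-0.12, 0.0241) and the proteasome (-0.09, 0.0241). Each of these 11 lists had 0 members past the test and adjusted p = 0.605 to 0.935 with an estimated correlation. The cholesterol enzyme Nsdhl stood at 4.5 ± 0.534 and 2.41 ± 0.442 TPM (adjusted p = 0.49) and the myelin protein Mag at 155 ± 24.6 and 101 ± 5.49 TPM. Without wild-type RNC 2 and knock-in RNC 3 the mitochondrially encoded list turned (0.834 and 0.166), and it ended without wild-type RNC 1 (0.385) and under quantile normalization (0.251), which also ended heat shock proteins (0.109) and the proteasome (0.191). Calls also ended for glutamate receptor genes (0.114), immediate early genes (0.635) and striatal markers (0.0534) without wild-type RNC 1, and for glutamate receptor genes without wild-type RNC 2 (0.113). They ended for heat shock proteins (0.241), the proteasome (0.0556) and myelin (0.17) without wild-type RNC 3, heat shock proteins without knock-in RNC 1 (0.0592), immediate early genes without knock-in RNC 2 (0.967), and 5 lists without knock-in RNC 3 (0.0849 to 0.254). The remaining 18 lists were not called, with medians from -0.18 to 0.23.

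**Figure D5:**
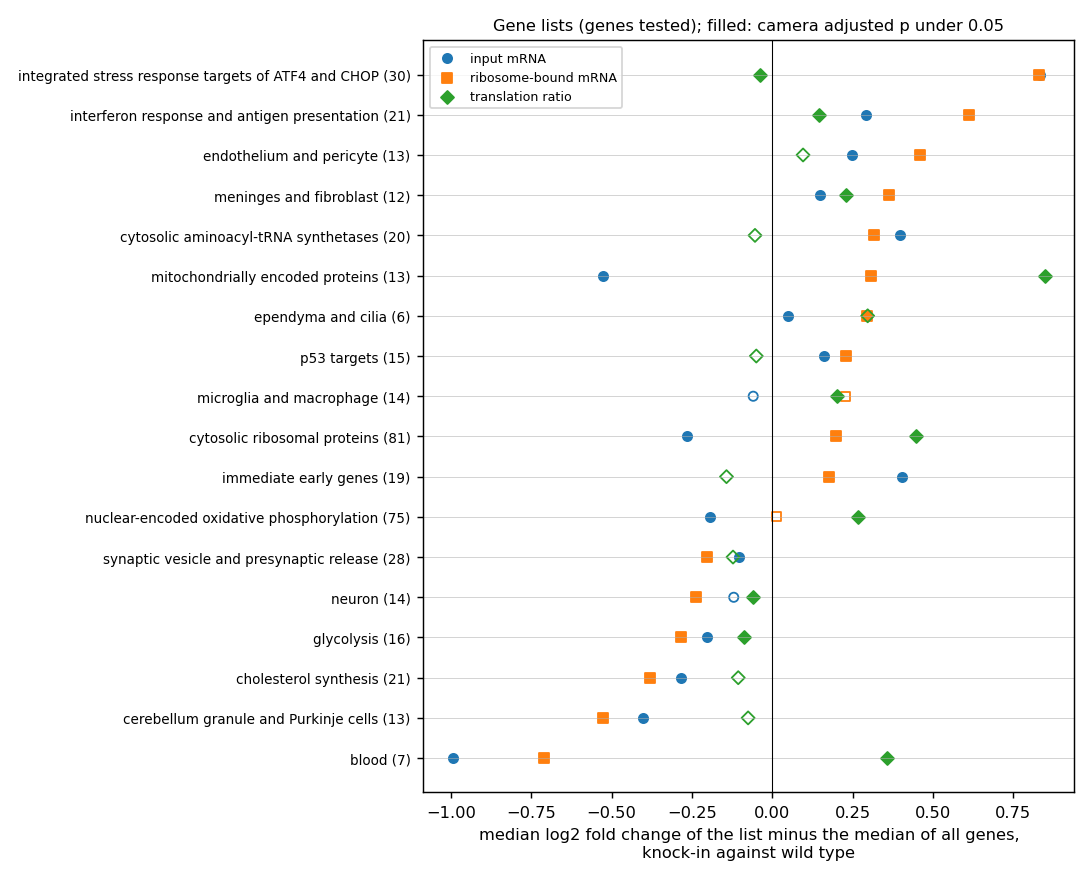
Median log2 change of gene lists relative to all tested genes, for lists called with a median of at least 0.2 in size, in the comparisons named on the plot; filled points have a camera adjusted p under the threshold of 0.05. Integrated stress response targets lie at 0.83 in input and RNC. The ribosomal protein and mitochondrially encoded lists are lower in input and higher in RNC, but in input they lie at 0.04 and -0.06 without the libraries numbered 3. In RNC the mitochondrially encoded list turns without wild-type RNC 2 or knock-in RNC 3.

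The third comparison asked whether mRNAs changed in RNC beyond their change in input, that is, whether the translation ratio differed between genotypes. Among groups, the 81 cytosolic ribosomal proteins had a median change of the ratio 0.45 above all genes, and 81 of 81 lay above the median of all genes. That call was lost at adjusted p = 0.0692 with an estimated correlation, and the median was 0.22 without the wild-type brain 3 libraries, 0.26 without those numbered 3 and 0.33 under quantile normalization. Rps29 lay 0.84 and Rps21 0.75 above it, with log2 changes of 0.46 ± 0.29 and 0.38 ± 0.28 (SE; n = 3 per genotype). The 13 mitochondrially encoded genes lay 0.85 above all genes (lost at adjusted p = 0.0692 with an estimated correlation), and at 0.48 without the libraries numbered 3 and 0.06 under quantile normalization. Their mRNAs are translated inside mitochondria by other ribosomes, so this ratio need not reflect their translation. They held from 16.9% (wild-type RNC 2) to 39.5% (knock-in RNC 3) of the summed TPM of an RNC library. Of these, mt-Co3 was at 0.49 ± 0.33 (-0.05 under quantile normalization). No single gene passed in limma (0 of 12232), with 51 at an unadjusted p under 0.05. This fit leaves out that input and RNC libraries were read as paired by brain. With the brain as a block 1 gene passed and 3265 had an unadjusted p under 0.05. The brain as a random effect called 1. Without the libraries numbered 3, 8 genes passed and 2459 had an unadjusted p under 0.05. The 0 calls of the unpaired fit thus do not show that ratios were unchanged. Leaving out knock-in input 2 or the brains knock-in 2 or 3 called 1 each. The median change of all genes was -0.37, and -0.13 without the libraries numbered 3.

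Ratios of the genes with the smallest p did not pass (adjusted p = 0.617 each). Septin2, a cytoskeletal GTPase, had a change of 1.52 ± 0.42, Dnase2a, a lysosomal nuclease, 1.95 ± 0.64, AL731706.2 2.32 ± 0.79, Fam229a 1.89 ± 0.68 and Bglap 0.65 ± 0.29. Clvs1, a neuronal clathrin vesicle protein, had -1.46 ± 0.43 (0.0108 with the block), Amh -1.20 ± 0.37, B3gnt7 -0.77 ± 0.26, Pknox1 -1.30 ± 0.44 and Cfb -1.33 ± 0.46. Wdr4 had -0.44 ± 0.38 and Mettl1 -0.38 ± 0.48, near the median of all genes. The stress gene Gdf15 had 0.60 ± 0.29, and the integrated stress response list stood at -0.04 by median and 0.07 by mean.

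Of the 41 lists, 11 were called for the ratio, none with an estimated correlation. The ribosomal protein list had a camera adjusted p of 2.55e-70 (adjusted p = 0.0692 with an estimated correlation) and kept its call without any 1 library. The mitochondrially encoded list had 9.49e-41 (adjusted p = 0.0692 with an estimated correlation) and was lost under quantile normalization (0.262), a scaling that cannot decide its change. Oxidative phosphorylation lay 0.27 above all genes (camera adjusted p = 5.07e-12; adjusted p = 0.204 with an estimated correlation) and turned without wild-type input 3 (0.4); its median was 0.06 without the libraries numbered 3. Blood markers lay 0.36 above (1.75e-05; adjusted p = 0.236 with an estimated correlation), and ended without knock-in input 1 (0.166) and knock-in RNC 3 (0.561). Meningeal (0.23, camera adjusted p = 0.00181), interferon (0.15, 0.00181) and microglial genes (0.20, 0.0293) were higher. Those of astrocyte (-0.09, 0.018), neuronal (-0.06, 0.0395) and glycolysis genes (-0.09, 0.042) were lower, and the stress response list was called higher (0.0293), each at adjusted p = 0.99 with an estimated correlation. Each of these 7 calls ended without some of the 12 libraries. Wild-type inputs 1, 2 and 3 ended 2, 2 and 4 of them (0.0585 to 0.847) and knock-in inputs 1, 2 and 3 ended 5, 5 and 4 (0.0706 to 0.682). Wild-type RNC 1, 2 and 3 ended 3, 5 and 3 (0.0573 to 0.88), and knock-in RNC 1, 2 and 3 ended 2, 1 and 4 (0.257 to 0.524). The block ended those of glycolysis (0.298), neuronal (0.198) and astrocyte genes (0.423). The number of lists called was 6 without knock-in input 1 and 7 without knock-in inputs 2 and 3, wild-type RNC 2 and knock-in RNC 3. The other 30 lists had medians from -0.14 to 0.30.

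The fourth comparison set RNC against input in wild-type brains and describes what the ribosome-bound fraction holds. Mitochondrially encoded mRNAs, which are translated inside mitochondria by other ribosomes, were depleted from RNC. Of 13, 7 fell and 6 did not pass, and 7 were lower when adjusted over the list alone. Of these, mt-Nd3 fell from 6123 ± 1213 TPM in input to 1628 ± 1108 TPM in RNC (SD, n = 3 each; log2 change -2.09 ± 0.36, adjusted p = 0.00912). Likewise mt-Atp8 fell by 1.61 ± 0.28, mt-Nd1 by 1.54 ± 0.37, mt-Atp6 by 1.51 ± 0.33, mt-Co3 by 1.32 ± 0.23 and mt-Co2 by 0.99 ± 0.35 (adjusted p = 0.00912 to 0.0386). Under quantile normalization, which holds genes near the top of every library close to no change, mt-Co2 turned to 0.22 and mt-Co3 stood at -0.02. Among nuclear genes, Fth1, the ferritin heavy chain whose translation is controlled by iron (chromosome 19, 9980600 to 9985111), fell from 1722 ± 160 to 787 ± 100 TPM (-1.13 ± 0.15, adjusted p = 0.005). Rps12 (chromosome 10, 23785183 to 23787383) fell from 238 ± 24.9 to 115 ± 8.98 TPM (-1.03 ± 0.16, adjusted p = 0.00878), Nrsn1, a neuronal vesicle protein, fell by 0.97 ± 0.32 and Selenow, a selenoprotein, fell by 0.97 ± 0.17.

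Genes higher in wild-type RNC were led by Map2, a dendritic microtubule protein (chromosome 1, 66175202 to 66442583), from 7.98 ± 6.97 TPM in input to 25.2 ± 6.94 TPM in RNC (2.19 ± 0.78, adjusted p = 0.0398). Igip rose from 156 ± 23.6 to 644 ± 205 TPM (adjusted p = 0.00961) and the zinc finger gene Zfp445 (chromosome 9, 122848910 to 122886851) from 8.51 ± 1.26 to 36.5 ± 2.53 TPM (1.99 ± 0.23, adjusted p = 0.00426). Hmgn5 (1.94), Zfp146 (1.90), Pgm2l1 (1.84), Htatsf1 (1.80), Ogt, the nuclear and cytosolic O-GlcNAc transferase (1.79), Bod1l (1.78) and Aff4 (1.75) followed. Relative to the median change of all genes, 0.67, these were 1.08 to 1.52, and under quantile normalization none of the 10 passed (adjusted p = 0.0665 to 0.278).

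In wild type 5591 genes differed between fractions, 5561 higher in RNC and 30 lower, with 7838 at an unadjusted p under 0.05. The libraries did not overlap for 6924 genes (56.6%, with 10% given by chance). This count moved with single libraries and with the scaling. Mitochondrially encoded transcripts held 47.0 ± 9.58% of the summed TPM in wild-type input and 23.8 ± 10.6% in RNC (SD, n = 3). A fall in their share raises that of every other gene. Quantile normalization called 35 higher and 84 lower, leaving out the mitochondrially encoded genes 21 higher and 35 lower, and the 6 wild-type libraries alone 1 gene. Leaving out wild-type RNC 1 or 2 gave 9, wild-type RNC 3 gave 8629 and wild-type input 3 gave 1654. The brain as a block gave 10708 (10658 higher), and leaving out the libraries numbered 3 gave 10784 (10697 higher). Of the genes named for this comparison as higher or lower, Zfp445 and Fth1 kept their calls without wild-type RNC 1 or 2, and the others were at 0.0619 to 0.154. Without wild-type input 3 the adjusted p was 0.105 for Map2, 0.0848 for Zfp146, 0.071 for Pgm2l1, 0.0542 for Ogt, 0.0523 for Aff4, 0.0552 for mt-Nd1 and 0.157 for mt-Co2. Nrsn1 ended without wild-type inputs 1 and 2 and wild-type RNC 3 (0.0628, 0.0581 and 0.0725), Map2 without knock-in inputs 1 and 2 and knock-in RNC 2 (0.0502, 0.0519 and 0.051), and mt-Co2 without the 3 knock-in inputs (0.0528, 0.0526 and 0.0549).

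Relative to all genes, the 81 cytosolic ribosomal protein mRNAs lay at -0.71 in wild-type RNC (camera adjusted p = 2.99e-82; adjusted p = 0.0436 with an estimated correlation), with 6 higher, 12 lower and 63 not past the test. It had 3 higher and 8 lower when adjusted over the list alone. Without the libraries numbered 3, 36 of the mRNAs were higher and 27 lower, and the list lay at -0.49. Rps29 (279 ± 66.0 to 146 ± 4.32 TPM) and Rps28 (58.2 ± 11.5 to 31.6 ± 1.03 TPM) fell and Rpl7 (215 ± 15.1 to 390 ± 53.4 TPM) rose. The mitochondrially encoded list lay at -1.62 (camera adjusted p = 6.03e-67, and 0.024 with an estimated correlation). Its call was lost under quantile normalization (0.187), which holds the most abundant genes close to no change and cannot decide it. Without the libraries numbered 3 the list lay at -1.69, with 13 of 13 lower. The proteasome lay 0.34 above all genes (camera adjusted p = 1e-07; adjusted p = 0.98 with an estimated correlation), with 29 of 31 higher and 29 when adjusted over the list alone, among them Psma4. Glycolysis (0.33; 15 of 16 higher, 16 when adjusted over the list alone), endoplasmic reticulum chaperones (0.26; 16 of 24 and 22) and myelin genes (0.13; 13 of 15 and 14) had camera adjusted p of 0.00141, 0.0155 and 0.0165, each lost at adjusted p = 0.98 with an estimated correlation. Examples were Ldhb (1.18 ± 0.23) and the chaperone Hspa5 (1.43 ± 0.25). Blood markers lay at -0.18 (4.3e-05; adjusted p = 0.371 with an estimated correlation), with 0 of 7 past the test, and under quantile normalization the call ended (0.2). The chaperone call ended without wild-type RNC 3 (0.111), and the myelin call without it (0.405), without wild-type inputs 1 and 2 (0.0635 and 0.0988) and under quantile normalization (0.235). With the brain as a block those of chaperones (0.0936), glycolysis (0.0704) and myelin (0.68) ended. Without wild-type input 3 the number of lists was 11 in place of 7. The other 34 lists had medians from -0.18 to 0.37.

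The fifth comparison set RNC against input in knock-in brains. Fth1 fell from 1836 ± 76.2 to 816 ± 58.3 TPM (SD, n = 3 each; log2 change -1.17 ± 0.15, adjusted p = 0.0155), and 2 more genes passed, which were chosen after their values were seen. Gm20594, a gene model, fell by 2.61 ± 0.24 (adjusted p = 0.000552) and 2610008E11Rik rose by 1.35 ± 0.20 (adjusted p = 0.0397). Of the 12232 genes, 2148 had an unadjusted p under 0.05 and 3441 did not overlap (28.1%, with 10% given by chance). The brain as a block called 4176 genes, 4105 higher and 71 lower, and leaving out the libraries numbered 3 called 9848, 9723 higher. Quantile normalization called 5 higher and 27 lower, and leaving out the mitochondrially encoded genes 1 higher and 10 lower. Leaving out wild-type input 3 gave 589 genes, and leaving out knock-in input 1, knock-in RNC 1 or knock-in RNC 2 gave 1. Fth1 lost its call without knock-in inputs 1, 2 and 3 (0.119, 0.0959 and 0.078) and knock-in RNC 1, 2 and 3 (0.0669, 0.18 and 0.057). Whether the fractions differ more in wild type than in knock-in is the test of the translation ratio above. That test called 0 genes without pairing by brain and 1 with the brain as a block.

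Among lists in knock-in RNC, mitochondrially encoded mRNAs lay at -0.70 (camera adjusted p = 3.01e-19, and 0.433 with an estimated correlation), with 0 of 13 past the test and 4 lower when adjusted over the list alone. Their call was lost under quantile normalization (0.521), which cannot decide their change. Without the libraries numbered 3 they lay at -1.27, with 13 of 13 lower. Ribosomal proteins lay at -0.28 (3.19e-14; adjusted p = 0.988 with an estimated correlation), with 0 of 81 past the test and 1 higher and 1 lower when adjusted over the list alone. Without the libraries numbered 3, 44 of them were higher and 14 lower. Rpl7 stood at 253 ± 31.5 and 471 ± 120 TPM and Rps12 at 264 ± 4.99 and 152 ± 7.7 TPM. Oxidative phosphorylation (0.19, camera adjusted p = 2.28e-10; 30 of 75 when adjusted over the list alone) and the proteasome (0.37, 7e-10; 23 of 31) were called higher, at adjusted p = 0.433 and 0.988 with an estimated correlation. Atp5h stood at 284 ± 22.9 and 511 ± 51.3 TPM and Psma4 at 49.9 ± 2.58 and 109 ± 23.1 TPM (adjusted p = 0.0754 each). With the block, Rpl7 (0.000751), Rps12 (0.00155), Atp5h (0.000968) and Psma4 (0.000368) passed. Mitochondrial ribosomal proteins (0.11, camera adjusted p = 0.000713; 1 member when adjusted over the list alone), glycolysis (0.21, 0.0253) and translation factors (0.15, 0.0491) were called higher, each at adjusted p = 0.988 with an estimated correlation. These 3 calls ended without knock-in input 1 (0.0545, 0.0847 and 0.0545). That of translation factors ended without knock-in input 3 (0.243), knock-in RNC 1 (0.142) and knock-in RNC 2 (0.127), that of glycolysis without knock-in input 2 (0.05) and knock-in RNC 1 (0.0594), and the first 2 with the block (0.161 and 0.116). Without knock-in input 3 or knock-in RNC 3 the number of lists was 11 in place of 7, and 34 lists were not called, with medians from -0.17 to 0.29.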

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

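Some tests were chosen only after their result was seen. They were the shared preparation of the libraries numbered 3, the unscaled means, the short mRNAs and, without the libraries numbered 3, the cerebellar markers and the gap between the second lists. The second lists were taken after the cerebellar pattern was seen. Their predictions over all libraries were written before their own result. For 11 gene lists, the change between genotypes differed between the fractions by a test of the difference itself, that is, the interaction of genotype and fraction with camera. Their median changes of the translation ratio relative to all genes were 0.446 for cytosolic ribosomal proteins, 0.848 for mitochondrially encoded proteins, 0.268 for oxidative phosphorylation and 0.356 for blood markers. They were 0.23 for meningeal, 0.146 for interferon and 0.201 for microglial genes. They were -0.0864 for astrocyte, -0.0598 for neuronal and -0.088 for glycolysis genes, and -0.0375 for integrated stress response targets, whose test pointed up. None of the 11 passed with an estimated correlation between genes (lowest adjusted p = 0.0692).

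By the list test, ribosomal protein mRNAs had a higher translation ratio in knock-in, 0.446 above all genes (0.07 against -0.37), with 0 of 81 members past the test and the call lost at adjusted p = 0.0692 with an estimated correlation. The tables argue against the wild-type brain 3 libraries alone, since without them the median was 0.216 (camera adjusted p = 1.05e-21). A bias for short mRNAs stays open: oxidative phosphorylation mRNAs, also short, reached 59.9% of the ribosomal protein median over all libraries, 68.5% under quantile normalization and 23.8% without the libraries numbered 3 (0.0607 ± 0.0158 against 0.255 ± 0.0168, SE over genes). Also open is a change shared by mRNAs with a 5' terminal oligopyrimidine tract. For 15 such genes outside the list the median was 0.148, above 99.2% of 10000 random lists matched on expression. Without the libraries numbered 3 it was 0.0882. The random lists draw genes and not brains, so that share does not measure chance between brains. The 51 translation initiation and elongation factors, not sorted by that tract, lay at 0.02 (camera adjusted p = 0.846). Whether genotype or an unequal recovery of ribosomal protein mRNAs between RNC preparations lies behind their higher ratio was not tested.

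By the list test, cerebellar granule and Purkinje cell markers were lower in knock-in in both fractions, with only Gabra6 of 13 past the test in each and the call lost at adjusted p = 0.0727 in input and 0.118 in RNC with an estimated correlation. The tables argue against the libraries numbered 3 as the cause, since without them the list lay at -0.492 in input and -0.507 in RNC. In a second list fixed for the purpose, 6 granule cell genes had a mean change relative to the median of all genes of -0.284 ± 0.0819 (SE over genes) in input and -0.338 ± 0.0658 in RNC, and 7 Purkinje cell genes of -0.223 ± 0.0608 and -0.0981 ± 0.0723; unscaled, the granule mean was 0.02 in input (-0.27 without the libraries numbered 3) and -0.40 in RNC. Less cerebellum in the tissue taken would lower both alike if both lists were equally confined to cerebellum, which was not measured. In RNC the gap between them was -0.24 ± 0.0978 (SE over genes), and -0.32 ± 0.112 without the libraries numbered 3. In input it was -0.0618 ± 0.102 over all libraries and -0.195 ± 0.0942 without those numbered 3. These errors run over genes measured in the same brains, and 0 genes of either list passed in either fraction. The gap therefore cannot decide whether less cerebellum was taken, and that cause stays open in both fractions. A lower abundance of granule cell transcripts with genotype may also account for the pattern, and the data on whole tissue cannot separate fewer cells from lower expression per cell.

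The libraries numbered 3 stood apart from numbers 1 and 2 in every group. The share of mitochondrially encoded transcripts is not the whole cause: after leaving those genes out and rescaling, the median log2 gap of wild-type input 3 was still -0.383, against -0.723 before. The sex of the brains predicts that knock-in 1 minus 2 resembles wild type 3 minus 1 and 2, and the correlations across genes were -0.200 in input and -0.0673 in RNC. A shared preparation or run of these libraries may be a cause, since their deviations correlated between genotypes at 0.211 in input and 0.583 in RNC. In input, however, the mitochondrially encoded share moved in opposite directions. It was 58.1% in wild type 3 against 41.5% and 41.4%, and 36.8% in knock-in 3 against 40.9% and 40.7%. The labels name no batch, and no biological explanation other than sex was tested.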

How the results depend on the processing

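The alternatives chosen only after the data were seen were leaving out the 4 libraries numbered 3, the number as a block in all 12 libraries, the Y-linked genes as a covariate, the brain as a random effect and leaving out the mitochondrially encoded genes. For mRNA in input, 32 genes became 21 with a filter of 5 TPM, 11 on the 6 libraries alone, 2 with the replicate block, 2608 without the libraries numbered 3, 248 with the number as a block in all libraries, 52 with the Y-linked covariate and 73 without the mitochondrially encoded genes, and 6 to 32 when single libraries were left out. For RNC, 21 became 49 with quantile normalization, 33 without a filter, 10 with a filter of 5 TPM, 84 with the replicate block, 3099 without the libraries numbered 3, 37 with the number as a block in all libraries and 47 without the mitochondrially encoded genes, and 7 to 37 when single libraries were left out. For the translation ratio, 0 became 1 with the replicate block, 8 without the libraries numbered 3 and 1 with the brain as a random effect, and 0 to 1 when single libraries or brains were left out.

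For RNC against input in wild type, 5591 became 119 with quantile normalization, 1 on the 6 libraries alone, 10708 with the replicate block, 10784 without the libraries numbered 3, 9119 with the number as a block, 8728 with the Y-linked covariate, 10818 with the brain as a random effect and 56 without the mitochondrially encoded genes, and 9 to 8629 when single libraries were left out. In knock-in, 3 became 32 with quantile normalization, 5 without the trend, 9 without a filter, 8 on the 6 libraries alone, 4176 with the replicate block, 9848 without the libraries numbered 3, 3187 with the number as a block, 46 with the Y-linked covariate, 4279 with the brain as a random effect and 11 without the mitochondrially encoded genes, and 1 to 589 when single libraries were left out. Fits on 6 libraries have fewer residual degrees of freedom, and filters test other genes. In wild type, the drop from 5591 to 56 shows that most calls depended on the share held by mitochondrially encoded transcripts. For the other shifts the cause was not tested.

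Lists called with camera were 22 in input, 23 in RNC and 11 for the ratio, and 7 in each fraction comparison. With an estimated correlation they were 0, 0, 0, 2 and 0, and with fry, which compares a list with no other genes, 4, 0, 0, 32 and 1. Without the libraries numbered 3 the fraction comparisons had 13 and 11. Leaving out single libraries gave 15 to 23, 17 to 24, 6 to 14, 6 to 11 and 5 to 11. Without the libraries numbered 3, calls in input ended for the proteasome (adjusted p = 0.0908), immediate early genes (0.14), ependymal markers (0.0545), GABA genes (0.668, turned) and heat shock proteins (0.99, turned). In RNC they ended for heat shock proteins (0.388), the proteasome (0.0996), myelin (0.248) and midbrain markers (0.388), for the ratio for glycolysis (0.191), astrocyte (0.823) and blood markers (0.0572), and in wild type for chaperones (0.156) and myelin (0.164). Quantile normalization ended those of the stress response (0.457), astrocyte (0.0652) and blood lists (0.0764) for the ratio, and of mitochondrial ribosomal proteins in knock-in (0.14).

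Adm2 and Trib3 in input kept their calls in all alternatives run for them, as did Adm2, Gdf15, Atf5, Trib3, Ddit3 and Nupr1 in RNC. Mettl1, not called in input at 0.20, turned to -0.35 without the libraries numbered 3, and mt-Co2 in wild-type RNC turned from -0.99 to 0.22 under quantile normalization; the cause was not tested. The replicate block also added list calls for myelin in input (adjusted p = 0.0123), GABA genes (0.00119) and autophagy (0.0405) in RNC, and hypothalamic markers (0.00826), synaptic vesicle genes (0.022), mitochondrial ribosomal proteins (0.000219) and glutamate receptor genes (0.0277) for the ratio. It added GABA genes in wild type (0.0462) and heat shock proteins in knock-in (0.0262) between fractions. Apart from these and the values given beside the results, it changed no other list call, and the genes it added are in its counts. Depth limits are unknown, since TPM keep no absolute depth.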

Other observations

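In this part, the comparison of changes between fractions and the splits of single lists were tests chosen only after the results were seen. Igf2, a growth factor of the meninges and choroid plexus, stood at 36.4 ± 17.6 TPM in wild-type and 108 ± 22.3 TPM in knock-in input (SD, n = 3; adjusted p = 0.0848), and at 50.6 ± 3.03 and 100.2 ± 21.6 TPM in RNC. Avp, the vasopressin precursor of the hypothalamus, stood at 38.1 ± 11.5 and 70.8 ± 23.2 TPM in RNC (adjusted p = 0.942, and 0.0323 with the block). Of the lists too small for a test, that of histones had 3 of 16 genes tested, with H1f2, a linker histone, at 82.1 ± 20 and 184 ± 42 TPM in input (adjusted p = 0.129). That of noncoding RNAs had 1 of 25 tested, Snhg11, with a change of 0.61 ± 1.15 in input. The pituitary list had 3 of 9 tested, of which Tshb, the beta chain of thyrotropin, was 0.587 ± 0.167 TPM in wild-type input and rose to 3.15 ± 0.458 TPM in wild-type RNC (adjusted p = 0.0049). The Y-linked list had 3 of 5 tested, with Ddx3y at a change of 0.97 ± 1.30 in input (adjusted p = 0.63).

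Across genes, which are not independent replicates, the change in input correlated with that in RNC at 0.586, and in the other 9 groupings of the 6 brains (each the input and RNC library of 1 genotype and number) at 0.339 to 0.776. Each of these 9 has brains of both genotypes on both sides in unequal numbers, so it still parts the genotypes in part. A correlation as high thus also arises where the genotypes are mixed, and both fractions share brains by number. In those 9 groupings, each fitted with both fractions regrouped together, at most 3 genes were called higher in both fractions, against 14 for the genotypes. All 3 were Y-linked, in the grouping that parts the brains with Ddx3y and Eif2s3y from those where both were listed at 0.

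Each comparison was repeated over the 10 ways to split its samples into groups of 3, the real one included and, within a fraction or genotype, with the other 6 libraries left in their groups, so the share of splits can never be under 0.1. Splits with as many genes as the real one numbered 1 in input (32 genes, highest other 1), 1 in RNC (21, highest other 0), 10 for the ratio (0, highest other 1), 1 in wild type between fractions (5591, highest other 1) and 2 in knock-in (3, highest other 3). For lists they numbered 1 in input (22, highest other 21), 1 in RNC (23, highest other 21), 1 for the ratio (11, highest other 7), 9 in wild type between fractions (7, highest other 21) and 5 in knock-in (7, highest other 11). Of the 10 splits, 4 part all 3 pairs of equal number as the real one does, and among the others of these the highest gene counts were 0, 0, 0, 0 and 2 and the highest list counts 16, 21, 7, 8 and 9. Between fractions in wild type, 1 split called 21 lists, 3 times the real 7. It set wild-type input 1 and RNC 1 and 2 against wild-type inputs 2 and 3 and RNC 3. That split still parts the fractions in part and keeps the libraries numbered 3 on the same side. Its count therefore cannot separate the fraction from another structure of the samples.

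Single lists were also followed over the splits. Each of the other 9 still holds part of the real contrast, so their medians are no reference without it. Of the called lists, those whose median exceeded in size that of all other 9 splits numbered 8 of 22 in input, 13 of 23 in RNC, 6 of 11 for the ratio, 5 of 7 in wild type between fractions and 6 of 7 in knock-in. The integrated stress response list lay at 0.83 in input and RNC, and in the other 9 splits its median was at most 0.335 and 0.432 in size. Cerebellar markers lay at -0.40 and -0.53 against at most 0.269 and 0.296, blood markers in input at -0.99 against 0.57, and aminoacyl-tRNA synthetases at 0.40 and 0.32 against 0.253 and 0.269. Ribosomal proteins for the ratio lay at 0.446 against 0.329, and mitochondrially encoded proteins at 0.848 against 0.744. Called lists that stayed within the other splits include blood markers in RNC (-0.71 against 0.734) and mitochondrially encoded proteins in RNC (0.31 against 1.07). In input they include interferon genes (0.29 against 0.476), endothelial markers (0.25 against 0.326), immediate early genes (0.40 against 0.527) and cholesterol synthesis (-0.28 against 0.316).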
